A study of Homo sapiens with 12 samples.

How the data were processed

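RNA from U2OS cells, a human osteosarcoma line, was sequenced from cells with a control short hairpin RNA or a short hairpin RNA against ZFC3H1, and each condition was read from whole cells, a cytoplasmic fraction and a nuclear fraction. The 12 libraries made 6 groups of 2 replicates, control or knockdown in total, cytoplasmic and nuclear RNA. Per the labels, libraries were made with a directional kit. Per the submitters' processing notes, STAR, DESeq and the hg19 build were used; their versions and roles are not given in the sources used here.

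The authors deposited, for each fraction, a table of 3′ UTR isoforms and a table of intronic polyadenylation (IPA) events, each with 4 libraries. Per the file headers, the 3′ UTR tables give the read count of the common 3′ UTR region (cUTR, upstream of the proximal poly(A) site) and of the alternative region (aUTR, between the proximal and distal sites). The deposited IPA tables give the read count of the region upstream of the intronic poly(A) site and the count of the cUTR, the same cUTR counts for genes in both kinds of table. Every listed count was at least 1 in all 4 libraries of its table. The deposited tables also give signal as coverage scaled to library depth (DRPM), the authors' log2 changes (RED for 3′ UTRs, REI for IPA) and the authors' p-values with their calls. In the 3′ UTR tables DRPM was the count divided by 1 factor per library; in the IPA tables the upstream DRPM was not a fixed multiple of the count, and the extra step is not given in the sources used here. The authors' 3′ UTR label UP goes with a log2 change below 0, so directions below were computed from the counts.

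The 3′ UTR tables held 8462 genes in total, 8069 in cytoplasm and 8370 in nucleus, and the IPA tables held 920, 881 and 866 events. Entries whose gene symbol had been turned into a date and repeated were left out of the 3′ UTR tables, 2 in cytoplasm and 4 in nucleus. The 7792 genes and 684 IPA events listed in all 3 fractions were joined. Events are placed by the hg19 positions in the tables. The annotation at hand (GENCODE, on GRCh38) was used only for the length and GC content of 3′ UTRs, by gene symbol, and no position was carried between the builds. How the authors chose the event for each gene is not given in the sources used here.

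Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. For IPA usage and for the 3′ UTR isoform ratio, the 2 regions of a feature were fitted together in edgeR's quasi-likelihood model of the counts, with a term for every library within the feature, so that the tested coefficient was the change between groups in the log2 ratio of the IPA region to cUTR, or of aUTR to cUTR. Features needed a mean of at least 10 reads in each region over the 12 libraries, which left 541 IPA events and 7112 genes with a 3′ UTR ratio. Gene expression was tested on the cUTR counts with TMM factors after edgeR's filterByExpr, which left 7654 genes. All 12 libraries entered 1 fit. The contrasts were knockdown against control in each fraction, the difference of the knockdown effect between cytoplasm and nucleus, and nucleus against cytoplasm in control cells, the last fixed beforehand for IPA and added after the data were seen for 3′ UTR ratio and expression. Each gave a two-sided p adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and a standard error (SE) from the fit. Expression and both ratios share the cUTR reads. Reported IPA levels are reads of the IPA region per 100 cUTR reads, as mean ± SD over 2 libraries. They are not scaled to the lengths of the regions, so they are not shares of transcripts.

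Named features were chosen by a rule fixed before the data were examined. In each contrast they were up to 10 rising and 10 falling features with the largest log2 change among those past the threshold, with both knockdown libraries beyond both control libraries, a mean of at least 20 reads per region over the libraries compared, and a single feature per gene. Where fewer than 3 passed in a direction, the 3 with the smallest p were taken and said not to pass. ZFC3H1 and up to 4 members of each gene list with the smallest p were added, and a gene named outside the rule is said to be so. The 19 lists held 580 genes and were also fixed beforehand: PAXT, NEXT and nuclear exosome factors; snoRNA host genes; mRNA export factors; cleavage and polyadenylation factors; U1 snRNP, SR protein and nuclear speckle factors; DNA damage response genes; p53 targets; ATF4 and unfolded protein response genes. They also covered interferon-stimulated genes, cell cycle genes, genes of secreted, ER and matrix proteins, receptor tyrosine kinases, genes with well known IPA sites, ribosomal protein genes, nuclear long noncoding RNAs, mitochondrial mRNAs, and markers of osteoblasts and mesenchyme, of epithelium and of leukocytes. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Overlaps between fractions were tested with Fisher's exact test.

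Reads in cUTR and aUTR regions summed to between 5528068 and 12326670 per library. The medians per library were 102 to 339 aUTR reads per gene and 17 to 37 reads per IPA event. The models were tested on simulated data drawn from each feature's mean and dispersion over all 12 libraries. In these, 200 changed features were placed in the knockdown cytoplasm libraries, and every group had the same dispersion. The models recovered 4.48%, 43.3% and 92.3% of IPA changes of 1.5-fold, 2-fold and 4-fold, and 1.49%, 21.2% and 81.8% of 3′ UTR changes. For expression the shares were 1.49%, 64.2% and 95.5%. False calls were 3.16%, 6.76% and 5.31% of those made, and 0 calls were made where no change was simulated. Replicates varied by more than sampling, with a chi-square per degree of freedom from 2.61 in control total to 15.5 in knockdown cytoplasm. The simulated rates, from equal dispersions, need not hold for the groups that varied more. The 2 regions of a feature were simulated independently, so the rates for the ratios need not hold where both regions vary together. The labels do not say that replicates were separate cultures, nor that fractions came from the same cultures, so p-values measure only the spread between these libraries.

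Alternatives fixed beforehand were a replicate block, DESeq2 size factors, limma on log2 ratios with a pseudocount of 0.5 or DESeq2 for expression, no filter, a minimum mean of 50 reads, a fit of only the libraries compared, an absolute log2 change of at least 1, and leaving out each library. Added after the data were seen were the authors' DRPM ratios in limma, aUTR as the IPA reference, counts thinned to equal sums of cUTR and aUTR reads per library, and cUTR plus aUTR reads for expression.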

Results

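RNA from U2OS cells carrying a control hairpin or a hairpin against ZFC3H1 was sequenced from whole cells and from cytoplasmic and nuclear fractions, with 2 libraries per condition and fraction. ZFC3H1 is a zinc finger protein that joins the helicase MTR4 in the PAXT connection, which brings polyadenylated nuclear RNA to the exosome for decay. The deposited tables count reads in 3′ UTR regions and upstream of intronic poly(A) sites, so the comparisons concern the use of intronic sites, the use of the distal 3′ UTR, and gene expression read from the proximal part of the 3′ UTR. Reads in 3′ UTR regions summed to 6891321 and 12326670 in the control total libraries and to 5528068 and 7799043 in the knockdown total libraries, in the order of replicates 1 and 2. The sums were 9606308 and 11453064 in control cytoplasm, 7541018 and 5659456 in knockdown cytoplasm, 11496982 and 8679061 in control nucleus and 5639612 and 6300935 in knockdown nucleus.

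The first question was whether ZFC3H1 mRNA was lower in the knockdown. Its level in total RNA was 74.5 ± 0.293 CPM (cUTR counts scaled to the TMM-adjusted size of each library) in control and 43.6 ± 1.51 in the knockdown (mean ± SD, n = 2 each), a log2 change of −0.77 (SE 0.23). In the nucleus it was 47.2 ± 17.3 against 24.0 ± 1.24, a log2 change of −0.96 (SE 0.25), and in the cytoplasm 11.01 ± 0.136 against 8.36 ± 0.908, a log2 change of −0.41 (SE 0.33). Every ZFC3H1 knockdown library lay below both control libraries of its fraction. Over all genes tested the adjusted p was 0.228 in total, 0.596 in cytoplasm and 0.109 in nucleus. The total change passed in a fit of the 4 total libraries alone (adjusted p = 0.0368) and the nuclear change passed with the replicate number as a block (adjusted p = 0.0432). The nuclear change was −0.54 without control nucleus replicate 2 and −1.31 without control nucleus replicate 1. Among PAXT, NEXT and exosome factors, the nuclear ZFC3H1 change also passed when adjusted over the list alone (adjusted p = 0.0292).

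**Figure D1:**
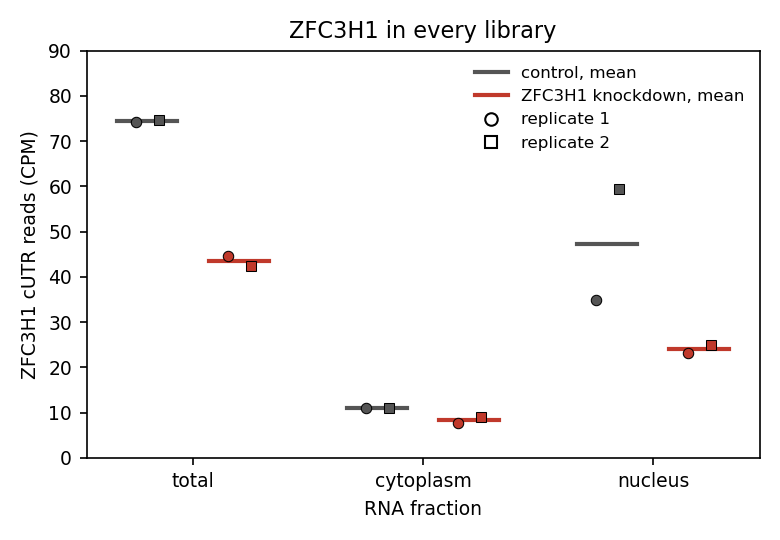
Expression of ZFC3H1 (CPM of cUTR reads) in each library, by fraction and condition; points are the 2 replicates and lines are group means. In total RNA the control mean is 74.5 and the knockdown mean is 43.6, and in each fraction both knockdown libraries lie below both controls.

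In total RNA, knockdown against control asked which intronic poly(A) sites were used more when ZFC3H1 was reduced. The IPA event of BRD3, a BET bromodomain protein, at hg19 chromosome 9, position 136932142, minus strand, went from 9.56 ± 2.20 to 197 ± 13.6 IPA reads per 100 cUTR reads (log2 change 4.31, SE 0.66, adjusted p = 3.37e-05). The event of the transcription factor CREB1 at chromosome 2, position 208395546, plus strand, rose 16.6-fold, from 62.7 ± 7.15 to 1025 ± 136 (log2 change 4.05, SE 0.34, adjusted p = 4.36e-08). The ubiquitin-conjugating enzyme variant UBE2V2 rose 13.2-fold from a low level, 1.01 ± 0.162 to 13.0 ± 1.19, and PCF11, a cleavage factor subunit that acts in 3′ end formation and termination, rose 12.3-fold (SE of the log2 change 0.38). PI4K2B, SLF2, GPR137C, CCDC71, MIER1 and UBR4 rose by 9.31-fold to 12.5-fold. Mean cUTR reads over the total libraries were 47.75 for BRD3, 40.75 for CREB1, 35.25 for PI4K2B and 31.5 for PCF11. The ratios of these genes rest on few reference reads, unlike that of UBE2V2 (1515). Of 541 events, 120 rose and 5 fell, the risers by a median of 3.81-fold. The falling events were in SYCE1L, ELP6, WASHC5, PPARG and KMT5B, with SYCE1L at chromosome 16, position 77236296, plus strand, going from 2318 ± 338 to 661 ± 13.0 (log2 change −1.81, SE 0.32, adjusted p = 0.000161).

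In the cytoplasm, the question was whether transcripts ending at intronic sites also rose outside the nucleus. CREB1 rose 56.4-fold, from 79.9 ± 33.3 to 4250 ± 928 IPA reads per 100 cUTR reads (log2 change 5.82, SE 0.37, adjusted p = 4.04e-10). TCAF1, a TRPM8 channel-associated factor, rose at chromosome 7, position 143598245, minus strand, from 1.59 ± 0.0563 to 89.5 ± 33.3, a 53.6-fold change (SE of the log2 change 0.36), and CCDC71 rose 32.5-fold at chromosome 3, position 49203100, minus strand (log2 change 5.02, SE 0.26, adjusted p = 2.93e-11). IQCK rose 57.8-fold from 9.69 ± 9.87, and MIER1, SLF2, ST3GAL3, UBR4, BRD3 and GSTCD rose by 26.3-fold to 44.2-fold. Mean cUTR reads over the cytoplasmic libraries were only 28.75 for CREB1, 23.75 for IQCK and 36.25 for BRD3, so these folds rest on few reference reads. They were 359.2 for TCAF1 and 295.5 for CCDC71. In all, 145 events rose and 6 fell, the risers by a median of 4.59-fold. The falling events were in SYCE1L (log2 change −2.35, SE 0.30), the myosin gene MYO5A, PPARG, ARMC8, TRAK1 and PARD3. The fall of MYO5A, to 0.354-fold (SE of the log2 change 0.45), turned to a log2 change of 0.78 when aUTR reads were the reference, and its 3′ UTR ratio fell as well.

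In the nucleus, where PAXT acts, BRD3 rose 20.4-fold (log2 change 4.35, SE 0.63), PCF11 19.4-fold (log2 change 4.28, SE 0.43) and the chaperone gene HSP90AA1 17.7-fold. HSP90AA1 IPA reads stayed rare beside its abundant mRNA, 0.0401 ± 0.0221 per 100 cUTR reads in control and 0.716 ± 0.0453 in the knockdown. UBE2V2, UBR4, ZFPM1, MIER1, SLF2, GPR137C and DENND1A rose by 11.3-fold to 15.8-fold. Mean cUTR reads over the nuclear libraries were 20.5 for PCF11 and 54.5 for BRD3, so their ratios rest on few reference reads. Of the events, 135 rose and 5 fell, the risers by a median of 3.77-fold. SYCE1L fell again (log2 change −1.83, SE 0.31), as did the m6A reader gene YTHDC1, ARMC8, the telomere protein gene TERF2 and an event at chromosome 2, position 110325327, minus strand, whose symbol is listed as a date and which was named after its values were seen.

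**Figure D2:**
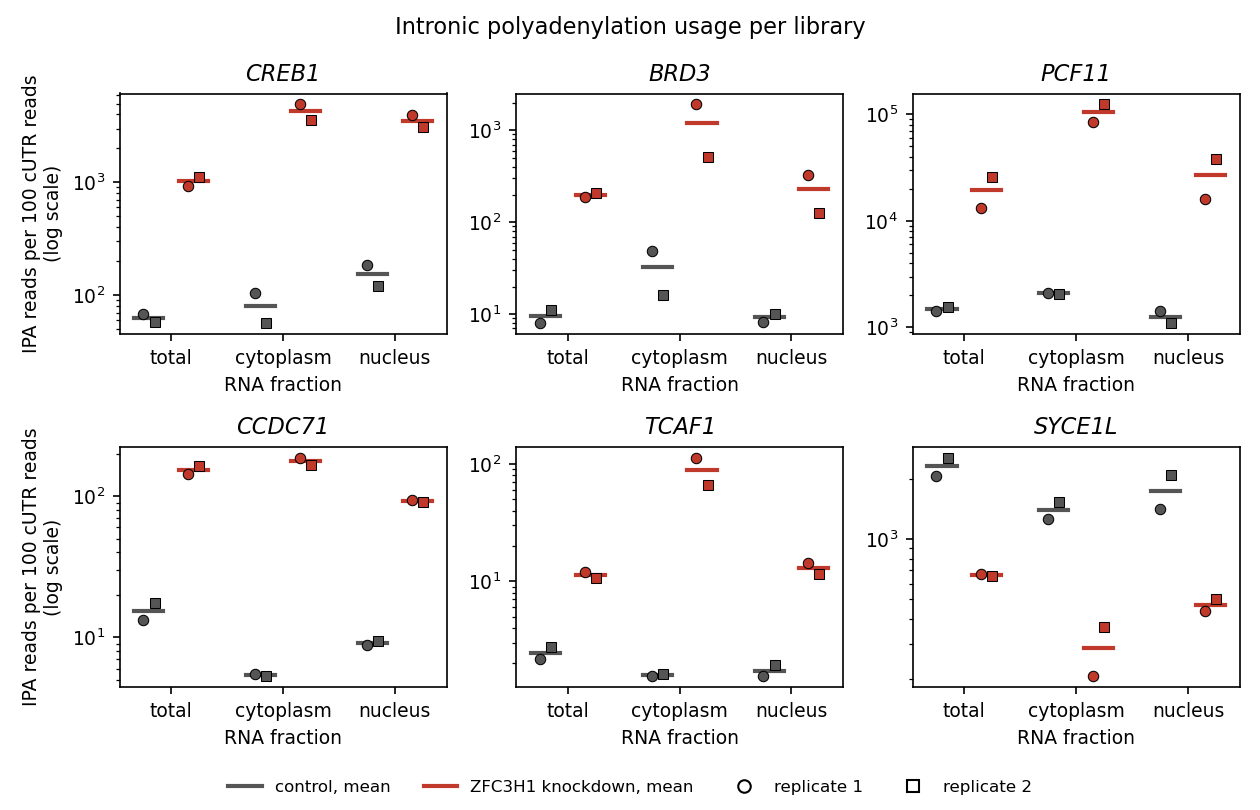
IPA reads per 100 cUTR reads (log axis) of the events of CREB1, BRD3, PCF11, CCDC71, TCAF1 and SYCE1L in each library, by fraction and condition. CREB1 goes from a control mean of 79.9 to 4250 in the cytoplasm, and SYCE1L goes down in each fraction, from 2318 to 661 in total RNA.

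The IPA rises were largely shared between fractions. Events in 101 genes rose in all 3 fractions and in 171 genes in at least 1. Cytoplasm and nucleus had 115 rising events in common where chance gave 36.2 (Fisher's exact test, p = 5.98e-67), total and cytoplasm 110 against 32.2, and total and nucleus 105 against 29.9. Across events the log2 changes in cytoplasm and nucleus had a Pearson correlation of 0.857. This value and the overlap test are over events, which are not independent replicates. All fractions were called in 1 fit with 1 estimate of spread per event, so calls can coincide more often than the chance counts assume. SYCE1L was the single event that fell in all 3, and 12 events fell in at least 1. The cUTR reads of SYCE1L, its reference, rose in the cytoplasm (log2 change 1.77, SE 0.25), so its fall there partly reflects the reference. The median log2 change over all events was 0.23 in total, 0.34 in cytoplasm and 0.27 in nucleus, and it lay between 0.22 and 0.46 in all pairs of a knockdown and a control library. The authors' deposited tables, by their call on a DEXSeq p-value (at most 0.0499 among called events, and not the adjusted p used here), put 159, 167 and 153 of these events up and 14, 15 and 16 down in total, cytoplasm and nucleus. Those calls held 120, 145 and 133 of the events that rose here and the 5, 6 and 5 that fell. With a minimum mean of 50 reads, 204 events were tested and 62, 66 and 63 changed.

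Of the lists, cleavage and polyadenylation factors had 6 measured IPA events, of which PCF11 and the cleavage stimulation factor gene CSTF3 rose in each fraction. CSTF3, at chromosome 11, position 33139486, minus strand, rose 3.98-fold in total (SE of the log2 change 0.28), 9.75-fold in cytoplasm and 6.79-fold in nucleus. PCF11 rose 47.8-fold in cytoplasm, where its cUTR was at 2.05 ± 0.0928 CPM in control, so that its ratio rests on few reads. Adjusted over the list alone, 2 rose in total and cytoplasm and 3 in nucleus, and the set test did not pass (adjusted p = 0.41, 0.532 and 0.165). Genes with well known IPA sites had 7 events, PCF11 and CSTF3 again among them. In these 2 rose in total, 3 in cytoplasm and 3 in nucleus, and adjusted over the list alone 2, 3 and 4 rose and NUP98 fell in cytoplasm. The set test for this list gave adjusted p = 0.41, 0.534 and 0.165. The other lists had fewer than 5 events each and were not tested as sets. In these lists, the events of EGFR, the histone methyltransferase gene NSD2 and the collagen prolyl hydroxylase gene P4HA1 rose in every fraction, EGFR by 2.02-fold to 2.17-fold, NSD2 by 1.96-fold to 2.21-fold and P4HA1 by 5.26-fold to 8.88-fold.

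The difference of the knockdown effect between cytoplasm and nucleus asked whether IPA transcripts rose more in either compartment. TCAF1 rose more in the cytoplasm by 2.86 on the log2 scale (SE 0.49, adjusted p = 0.0072), and GSTCD, at chromosome 4, position 106631123, plus strand, by 2.69 (SE 0.56, adjusted p = 0.0334). The TCAF1 event went from 1.74 ± 0.258 to 12.9 ± 2.08 in the nucleus and that of GSTCD from 2.70 ± 0.696 to 11.1 ± 2.10, while GSTCD went from 1.10 ± 0.501 to 27.8 ± 1.84 in the cytoplasm. CCDC71 had a difference of 1.68 (adjusted p = 0.068), and the smallest p in the other direction belonged to GGNBP2 (−2.55), GSTO2 (−0.99) and STX8, none passing (adjusted p = 0.518). The 2 calls rest on single libraries, as without control cytoplasm replicate 2 or control nucleus replicate 2 the count was 0, and without knockdown cytoplasm replicate 1, knockdown cytoplasm replicate 2 or knockdown nucleus replicate 1 it was 1, while without control nucleus replicate 1 it was 3. It was also 0 in a fit of only the 8 libraries compared and with the authors' DRPM, 1 after thinning, 3 with the replicate block, 4 with limma and 12 with aUTR as the reference.

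In control cells, nucleus against cytoplasm asked how IPA usage differed between the fractions before the knockdown. The event of the chromatin regulator gene ANKRD11 at chromosome 16, position 89353069, minus strand, had 73.7 ± 23.7 reads per 100 cUTR reads in the nucleus and 625 ± 107 in the cytoplasm (log2 change −3.10, SE 0.26, adjusted p = 1.05e-07), and that of the microfibril gene FBN1 42.2 ± 8.16 and 373 ± 144. RBBP6, GIGYF2, RPGRIP1L, MICAL3 and BPTF were also lower in the nucleus. The events of ZNF606 (9.53-fold, SE of the log2 change 0.54), ST3GAL3 (8.53-fold), BCL11A (6.80-fold), MRPS6 (5.78-fold, SE of the log2 change 0.30), RPRD1A, SMAD3 and SCAF4 were higher in the nucleus. In all 33 events were higher in the nucleus and 70 in the cytoplasm. The count of 103 was 55 without control cytoplasm replicate 1 (15 higher in the nucleus and 40 in the cytoplasm), 62 without control nucleus replicate 2 (12 and 50), 90 without control nucleus replicate 1 (41 and 49) and 70 without control cytoplasm replicate 2 (22 and 48), and it was 57 with a minimum mean of 50 reads.

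For 3′ UTR isoforms, the ratio of aUTR to cUTR reads asked whether the distal part of the 3′ UTR was used more or less. In total RNA the kinase gene PSKH1 went from 0.245 ± 0.0149 to 2.16 ± 0.0450 aUTR reads per cUTR read (8.80-fold, SE of the log2 change 0.30, adjusted p = 0.000273), with the potassium channel gene KCNH3 rising 7.05-fold, the pyruvate carboxylase gene PC 5.10-fold, NCAPH2 4.71-fold and ABHD17A 4.53-fold. NFE2L2, which encodes the oxidative stress factor NRF2, rose by 1.91 on the log2 scale. The ratio fell for TBPL1 (log2 change −2.61, SE 0.44), HMGN2, EXOC6B, CDKN3, HMGA2 (−1.43, SE 0.21) and the splicing factor gene RBFOX2 (−1.35, SE 0.17). Of 7112 genes, 14 rose and 46 fell. The count of 60 was 2 without control replicate 1, 8 without knockdown replicate 1, 2 without control replicate 2 and 21 without knockdown replicate 2, and it was 201 with the replicate block, 14 with limma and 329 in a fit of the 4 total libraries.

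In the cytoplasm, distal 3′ UTR use was lower for many genes. MYO5A went from 1.27 ± 0.192 to 0.261 ± 0.0905 aUTR reads per cUTR read (log2 change −2.28, SE 0.29, adjusted p = 0.00101), the ER-shaping GTPase gene ATL3 from 1.42 ± 0.721 to 0.214 ± 0.0674 (−2.67, SE 0.37, adjusted p = 0.00145), and PLLP from 0.482 ± 0.164 to 0.0493 ± 0.0132 (−3.20, SE 0.47, adjusted p = 0.00251). GPR3, TBPL1, TNIP1, the DNA repair nuclease gene MRE11 and LPP also fell, as did the chromatin protein gene HMGA2 (−1.83, SE 0.23), named here after its values were seen. PC (6.61-fold), ABHD17A (5.73-fold, SE of the log2 change 0.19), NCAPH2, PSKH1, TXNRD2, IER5L, USP49 and PXDC1 rose. In all 354 genes fell and 27 rose, and the median log2 change over genes was −0.20, with −0.24 to −0.16 in the pairs of a knockdown and a control library. By their call on an adjusted p (at most 0.0999 among called genes, a looser threshold than the one here), the authors' deposited tables had 532 falls and 38 rises among these genes in the cytoplasm, 492 and 82 in total, and 133 and 65 in the nucleus. Those calls held 313 of the 354 falls and 24 of the 27 rises found here in the cytoplasm, 46 of 46 and 14 of 14 in total, and 11 of 11 and 22 of 23 in the nucleus, where the authors' calls had more falls than rises and those here more rises. The count of 381 was 198 without control replicate 1, 155 without knockdown replicate 1, 54 without control replicate 2 and 666 without knockdown replicate 2. It was 678 with the replicate block, 37 in a fit of the 4 cytoplasmic libraries and 232 with an absolute log2 change of at least 1. The fit of the 4 total libraries gave more genes than that of the 4 cytoplasmic libraries. A larger count in cytoplasm than in total thus rests on the joint fit. That fit gave all groups 1 estimate of spread per gene. Replicate cUTR counts varied most in knockdown cytoplasm (chi-square per degree of freedom 15.5, against 2.61 in control total), so the cytoplasmic count of 381 may be too high.

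In the nucleus, KCNH3 rose 12.7-fold, from 0.382 ± 0.244 to 4.37 ± 0.866 aUTR reads per cUTR read (SE of the log2 change 0.35, adjusted p = 0.000134), PSKH1 10.5-fold, PC 7.65-fold, NCAPH2 5.66-fold and ABHD17A 5.35-fold. The exosome subunit gene EXOSC1 rose 3.66-fold (SE of the log2 change 0.23). MYO5A (log2 change −2.02, SE 0.24), HMGA2 (−1.58, SE 0.23), the deubiquitinase gene USP3, RBFOX2 and PNN fell. In all 23 genes rose and 11 fell, and the median over genes was −0.0031, with library pairs from −0.10 to 0.07. The nuclear count of 34 was 18 without control replicate 1, 7 without knockdown replicate 1, 102 without control replicate 2 (92 rises and 10 falls) and 6 without knockdown replicate 2. It was 121 with the replicate block, where falls outnumbered rises (51 rises and 70 falls), 13 with limma and 20 in a fit of the 4 nuclear libraries.

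All 11 genes that fell in the nucleus fell in the cytoplasm, where chance gave 0.547 (Fisher's exact test, p = 4e-15). All 14 that rose in total rose in the nucleus, where chance gave 0.0453. Genes are not independent replicates. The fractions were also called in 1 fit with 1 estimate of spread per gene, so calls can coincide more often than these chance counts assume. The difference of the knockdown effect between cytoplasm and nucleus had a median of −0.20 over genes. No gene passed in edgeR (lowest adjusted p = 0.295) or in limma, and 633 had an unadjusted p under 0.05, 595 of them lower in the cytoplasm. The smallest p in each direction, none passing, belonged to NDUFAF3 (−1.78, SE 0.33), HIF1AN (−1.20), PLLP (−4.48), ARF4 (1.76), DGAT2 and PHF20. The count was 38 without control nucleus replicate 2 and 2 without knockdown cytoplasm replicate 1.

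**Figure D3:**
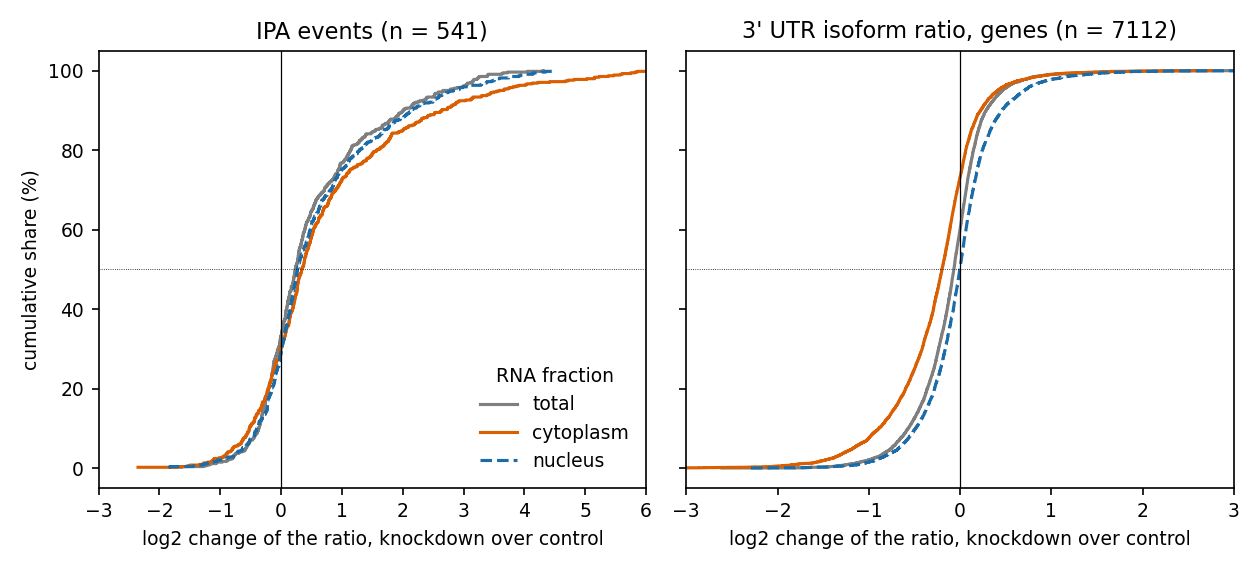
Cumulative share (%) of features against the log2 change of knockdown over control in each fraction, for 541 IPA events and for the 3′ UTR ratio of 7112 genes. The IPA medians lie above 0, at 0.23 to 0.34, with 66.7% to 70.6% of events above 0. The 3′ UTR median of the cytoplasm lies below 0, at −0.20, with 26.9% of genes above 0.

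On knockdown, no list passed the set test of its 3′ UTR ratio in any fraction or in the difference between cytoplasm and nucleus, the lowest adjusted p being 0.0633 for ribosomal protein genes in total RNA. Of 27 U1, SR protein and speckle factors, PNN fell in all 3 fractions (log2 changes −1.22, −1.60 and −1.14 in total, cytoplasm and nucleus), and the SR protein genes SRSF6 and SRSF10 fell in the cytoplasm, 3 members also when adjusted over the list alone. Of 19 PAXT, NEXT and exosome factors, EXOSC1 rose in total and nucleus, and EXOSC5 (−2.03) and NCBP3 (−1.02) fell in the cytoplasm. The export factor gene ALYREF (−1.62) fell in the cytoplasm, as did MRE11 of the DNA damage genes, LAMC1, FOXN3, CD44 and RPL38 and RPL14 of 32 ribosomal protein genes, 6 of which fell when adjusted over the list alone.

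Gene expression, from cUTR reads, asked which mRNAs changed in amount. In total RNA KLHL31 went from 4.72 ± 0.788 to 63.4 ± 9.53 CPM (13.6-fold, SE of the log2 change 0.33, adjusted p = 6e-05), the autophagy gene VMP1 from 254 ± 2.66 to 1010 ± 15.1 (3.97-fold, SE of the log2 change 0.19), and the BMP antagonist gene GREM1 rose 4.75-fold. The interleukin 6 receptor gene IL6R, AATK, FGFBP3 and MAT2A, which makes S-adenosylmethionine, rose as well. PSIP1, which encodes the chromatin tether LEDGF, fell from 117 ± 2.70 to 30.0 ± 6.99 (log2 change −1.94, SE 0.24, adjusted p = 0.00212), the mitochondrial import gene TIMM17A by a log2 change of −1.61 (SE 0.23), and EPDR1, PSKH1, VAMP3, TGFBR3 and ENTPD6 fell. For PSKH1 the ratio of aUTR to cUTR rose 8.80-fold in total RNA, so its fall in cUTR reads need not be a fall of the whole mRNA. In all 15 genes rose and 12 fell. The count of 27 was 3 without control replicate 1, 5 without knockdown replicate 1 and 3 without control replicate 2. It was 104 with the replicate block, 58 with DESeq2, 129 in a fit of the 4 total libraries, 99 with aUTR reads added and 17 with a minimum mean of 50 reads.

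In the cytoplasm 39 genes rose and 37 fell. PRRT2 rose 6.47-fold (SE of the log2 change 0.35), the receptor gene CSF1R 4.33-fold, VMP1 4.06-fold (SE of the log2 change 0.19), and FGFBP3, PLLP, HMGA2, SYCE1L and the cyclin gene CCND2 by 3.37-fold to 4.28-fold. The growth factor receptor gene FGFR1 fell from 84.3 ± 6.62 to 24.6 ± 1.97 CPM (log2 change −1.78, SE 0.22, adjusted p = 0.00108), and TGFBR3, PSIP1 (−2.15, SE 0.35), SOCS5, TLX2, PSKH1 and TIMM17A fell. In the nucleus 27 rose and 15 fell, with KLHL31 up 16.5-fold (SE of the log2 change 0.39), GREM1 5.16-fold, HMGA2 4.26-fold and VMP1 4.07-fold. PSKH1 (log2 change −2.03), PSIP1 (−1.87, SE 0.25), TIMM17A, TGFBR3, ENTPD6 and FGFR1 (−1.01) fell in the nucleus. Cytoplasm and nucleus had 18 rising genes in common where chance gave 0.138 and 10 falling genes where chance gave 0.0725. Both fractions were called in 1 fit with 1 estimate of spread per gene, so these chance counts may be too low. PSKH1, HMGA2, PLLP and SYCE1L also changed in a ratio in the opposite direction, and those ratios have the same cUTR reads below the line. The cytoplasmic count of 76 was 21 without control replicate 1, 29 without knockdown replicate 1, 10 without control replicate 2 and 299 without knockdown replicate 2, and it was 245 with the replicate block, 141 with DESeq2, 44 in a fit of the 4 libraries and 239 with aUTR reads added. The nuclear count of 42 was 5 without control replicate 1, 4 without knockdown replicate 1 and 20 without control replicate 2, and it was 148 with the block, 115 with DESeq2 and 116 with aUTR reads added.

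The expression effect did not differ between cytoplasm and nucleus for any gene at the threshold (edgeR and DESeq2 both 0, lowest adjusted p = 0.738), with an unadjusted p under 0.05 for 464 genes. The smallest p belonged to LIN54 (−1.84), ARF4, PARD6B, SLC3A2, COL11A1 and EEF1A2, none passing. Residuals by replicate number correlated between cytoplasm and nucleus for expression (0.409 in control and 0.36 in the knockdown). No fit paired the fractions by number within a treatment, so this test may miss differences, and the count of 0 does not show equal effects.

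Cell cycle and mitosis genes had median log2 changes of −0.22, −0.27 and −0.27 in total, cytoplasm and nucleus. Of the 29, 0 passed over all genes in edgeR in each fraction and 0, 0 and 2 in DESeq2, and 5, 7 and 7 had an unadjusted p under 0.05, all downward. Adjusted over the list alone 2 fell in total, 0 in cytoplasm and 4 in nucleus. The ribonucleotide reductase gene RRM2 had log2 changes of −0.62 in total and −0.70 in nucleus, the mitotic kinesin gene KIF20A −0.65 in total, and E2F1 −0.82 in nucleus. The set test at a preset correlation passed in each fraction (adjusted p = 0.000804, 0.0129 and 0.00173), but with an estimated correlation in none (adjusted p = 0.0571, 0.139 and 0.0714). Genes of secreted, ER and matrix proteins, 35 measured, with 0 past the threshold in edgeR, 1, 1 and 2 in DESeq2 and 2, 6 and 8 at an unadjusted p under 0.05, passed the preset test downward in total and nucleus (adjusted p = 0.0471 and 0.0378), not with an estimated correlation (adjusted p = 0.702 and 0.793). Their member with the smallest p, the matrix gene TNC, had the opposite sign (2.36-fold, 3.03-fold and 2.82-fold up), and adjusted over the list alone, TNC rose in cytoplasm and nucleus and 2 members fell in the nucleus. No other list passed the set test in any fraction, with adjusted p of at least 0.183.

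In the remaining lists few genes changed. Of 22 export factors DDX39B rose in the cytoplasm (1.76-fold, adjusted p = 0.0387), and of 18 receptor tyrosine kinases FGFR1 fell in cytoplasm and nucleus. In the lists of 19 PAXT, NEXT and exosome factors, 18 cleavage and polyadenylation factors, 28 U1, SR protein and speckle factors, 28 DNA damage genes and 15 p53 targets, 0 passed over all genes in any fraction in edgeR. The same held for 19 ATF4 and unfolded protein response genes, 19 genes with well known IPA sites, 35 ribosomal protein genes, 21 mitochondrial mRNAs, 9 osteoblast and mesenchymal markers and 5 epithelial markers. With DESeq2 1 factor of the PAXT list, 1 p53 target and 1 U1, SR protein or speckle factor passed in cytoplasm, 2 of the last list in nucleus, 1 ATF4 and unfolded protein response gene in cytoplasm and in nucleus, and 1 epithelial marker in nucleus. At an unadjusted p under 0.05, in total, cytoplasm and nucleus, were 2, 2 and 1 PAXT factors, 0, 0 and 3 cleavage factors, 3, 6 and 2 U1, SR protein and speckle factors, 2, 3 and 4 DNA damage genes, and 4, 5 and 4 p53 targets. The counts were 2, 3 and 4 ATF4 genes, 0, 1 and 0 genes with known IPA sites, 0, 1 and 1 ribosomal, 1, 1 and 3 mitochondrial, 2, 3 and 2 osteoblast and 2, 2 and 3 epithelial genes. Adjusted over the list alone, EXOSC4 and EXOSC5 rose in the cytoplasm. The ratio of aUTR to cUTR fell there for EXOSC5, so its rise in cUTR reads need not be a rise of the whole mRNA. Also adjusted over the list alone, the p53 target CDKN1A rose and SESN1 fell in the cytoplasm, and the p53 target RRM2B rose in the nucleus. By the same adjustment, SNRPA of the U1 list and the osteoblast and mesenchymal marker ENG rose in the cytoplasm, and FGFR1 fell also in total. Likewise adjusted, the stress gene DDIT4 rose in total and cytoplasm, and SLC7A5 fell in total and nucleus. In those terms 1 epithelial marker rose in each fraction, MAL2 in total (2.16-fold) and EPCAM in cytoplasm (2.00-fold) and nucleus (2.20-fold). Lists with fewer than 5 measured genes were 4 snoRNA host genes, 3 interferon-stimulated genes, 2 leukocyte markers and nuclear long noncoding RNAs, of which 0 were measured. Of these CSF1R, a leukocyte marker, rose in cytoplasm and nucleus, and the other leukocyte marker, CD68, did not pass over all genes in any fraction. Adjusted over the list alone CSF1R rose in each fraction, CD68 rose in the cytoplasm and the interferon-stimulated gene IRF9 fell in the nucleus.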

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

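The tests of read depth for both patterns below, the test of a general intronic rise and the test of single libraries for the 3′ UTR pattern were chosen only after the result was seen.

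The IPA events of TCAF1 and GSTCD rose more in the cytoplasm than in the nucleus, a difference between fractions that was tested itself. It was 2.86 on the log2 scale for TCAF1 (adjusted p = 0.0072) and 2.69 for GSTCD (adjusted p = 0.0334), and it stood out because the 2 fractions gave unequal effects of the same knockdown. The count of such events was 0 without control cytoplasm replicate 2 or control nucleus replicate 2 and 1 without knockdown cytoplasm replicate 1, knockdown cytoplasm replicate 2 or knockdown nucleus replicate 1, against 2 with all libraries. The IPA event of MYO5A stood out because both knockdown libraries lay above both controls in total RNA and below them in cytoplasm and nucleus, though only the cytoplasmic change passed the threshold (adjusted p = 0.751 in total and 0.235 in nucleus), with log2 changes that were 1.80 higher in total than in cytoplasm and 1.22 higher in total than in nucleus, and these differences were not tested. The 3′ UTR ratio of PXDC1 stood out in the same way, with the knockdown libraries below the controls in total (adjusted p = 0.604, not past the threshold) and above them in cytoplasm, and with a difference of −2.26 between the log2 changes that was not tested. For PLLP the 3′ UTR ratio moved in opposite directions in cytoplasm and nucleus, with a difference of −4.48 whose test did not pass (adjusted p = 0.295).

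The 1st pattern weighed is the rise of IPA usage in the knockdown libraries of all 3 fractions. Lower read depth of the knockdown libraries is argued against only as a source of calls through unequal counts. With all libraries thinned to the same sum of cUTR and aUTR reads, which did not make their IPA reads equal, 110, 124 and 111 of 474 events rose in total, cytoplasm and nucleus. In the fraction with the lowest share the count was 82.2% of the earlier one, not necessarily of the same events. Thinning keeps the expected ratio, so an effect of depth on the ratio itself was not tested. Fewer reads in the cUTR reference is argued against, since the IPA reads themselves, scaled to library depth, accounted for 91.1% of the median change of the ratio in total, 95.8% in cytoplasm and 94.5% in nucleus. A general rise of intronic or unspliced reads shared by all events is argued against as the whole cause, since with the median change over all events taken out of the knockdown libraries 99, 113 and 109 of the 120, 145 and 135 rises remained in total, cytoplasm and nucleus, and with the median gain per cUTR read taken out instead 95, 109 and 101 remained, 74.8% in the fraction that kept least, while the falls went from 5, 6 and 5 to 12, 31 and 17 under the 1st correction and to 56, 83 and 49 under the 2nd. A candidate explanation that stays open, only as a hypothesis that was not tested itself, is that less ZFC3H1 leaves more IPA transcripts undegraded. An effect of the hairpin on other genes and a rise of unspliced reads that varies between introns stay open too, untested.

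The 2nd pattern is the lower ratio of aUTR to cUTR in the cytoplasm of the knockdown, with a median log2 change of −0.20 over genes. Thinning cannot decide on lower read depth, since it draws aUTR and cUTR reads at the same share and so keeps the expected ratio. The median after thinning was −0.19, within the SD of the library pairs (0.0447). It left 249 falls and 19 rises, against 354 and 27 before, and lower read depth stays open. A single library that stands apart is argued against, since the highest median of the 4 library pairs was −0.16. Coverage or RNA integrity that scales with 3′ UTR length stays open, and the bound set for it beforehand was met. The change fell with length across 7103 genes (Spearman's rho −0.183, interval −0.207 to −0.161). Medians were −0.16, −0.12, −0.18 and −0.38 in 4 equal groups of genes from the shortest 3′ UTRs (median length 497 nucleotides) to the longest (4741.5). The fall was thus not steady and was larger mainly in the longest group, while the nucleus had a rho of −0.258 without a shift of its median. GC content of the 3′ UTR stays open as well, since its rho of 0.0935 differed from 0 but its interval (0.0713 to 0.118) held both smaller and larger values than the bound of 0.1 set beforehand. These correlations are across genes, which are not independent replicates, and an effect of ZFC3H1 on distal 3′ UTR use in the cytoplasm stays open, untested.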

How the results depend on the processing

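The alternatives that use the authors' DRPM, aUTR as the IPA reference, thinned libraries, or cUTR plus aUTR reads, and all those of the 3′ UTR ratio and expression between nucleus and cytoplasm, were chosen only after the results were seen.

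IPA usage changed in 125, 151 and 140 events in total, cytoplasm and nucleus, and over the alternatives other than a minimum mean of 50 reads the counts stayed within 1.5 times these. With that minimum only 204 events were tested, and 62, 66 and 63 changed, with 57 instead of 103 between nucleus and cytoplasm. With 1 library left out the counts were 94 to 105 in total, 122 to 156 in cytoplasm and 96 to 137 in nucleus, and 55 to 90 between nucleus and cytoplasm. In these fits a lone library is assumed to vary like the other groups. The median change stayed above 0 in every alternative run, 0.186 to 0.300 in total (0.23 with all libraries), 0.304 to 0.435 in cytoplasm (0.34) and 0.255 to 0.361 in nucleus (0.27) with a library left out. It was 0.305 in total with the authors' DRPM and 0.342 with aUTR as the reference (454 events tested), and 0.273 in cytoplasm with the minimum of 50 reads and 0.625 with aUTR as the reference; the cause was not tested.

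The IPA difference between cytoplasm and nucleus, 2 events, was 4 with limma, 0 in a fit of only the libraries compared, 0 with the authors' DRPM, 12 with aUTR as the reference, 1 after thinning (to equal sums of cUTR and aUTR reads) and 0 to 3 with a library left out. With aUTR as the reference 2 named events reversed, MYO5A in cytoplasm (0.78, adjusted p = 0.27) and GGNBP2 in the difference (0.0733, adjusted p = 0.995). The cause was not tested.

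The replicate block, which pairs libraries by replicate number, moved the 3′ UTR counts from 60 to 201 in total, 381 to 678 in cytoplasm and 34 to 121 in nucleus, and the expression counts from 27 to 104, 76 to 245 and 42 to 148. The IPA counts became 133, 154 and 147. Of 15 pairs of groups, residuals by replicate number correlated at over 0.1 in 8 for expression, 6 for IPA and 5 for 3′ UTRs (−0.0849 to 0.496, −0.143 to 0.158 and −0.0323 to 0.238), so the numbers do not pair the libraries throughout, though for expression they correlated in each pair of fractions of the same treatment (0.174 to 0.496). In a fit of only the libraries compared, which has fewer samples, 329, 37 and 20 genes changed in 3′ UTR ratio in total, cytoplasm and nucleus, and 129 in total and 44 in cytoplasm in expression. With limma the 3′ UTR counts were 14 in total and 13 in nucleus, and with an absolute log2 change of at least 1 the cytoplasmic count was 232. DESeq2 gave 58, 141 and 115 genes for expression, cUTR plus aUTR reads gave 99, 239 and 116, and a minimum of 50 reads gave 17 in total among 5881 genes. The cause was not tested, except that the stricter minimum tests fewer genes.

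With 1 library left out, the 3′ UTR counts were 2 to 21 in total, 54 to 666 in cytoplasm and 6 to 102 in nucleus, and 0 to 38 for the difference between cytoplasm and nucleus (38 without control nucleus replicate 2). The medians were −0.0892 to −0.0579, −0.226 to −0.162 and −0.0726 to 0.0551, so the cytoplasmic fall kept its sign, while the nuclear median was above 0 without control nucleus replicate 2 (0.0551) or knockdown nucleus replicate 1 (0.00693). The expression counts were 3 to 19, 10 to 299 and 4 to 59. The highest cytoplasmic counts of both came without knockdown cytoplasm replicate 2 and the lowest without control cytoplasm replicate 2, and the report gives some of the others by library. Counts were 2620 to 3023 between nucleus and cytoplasm (3635 with all libraries, 1958 with an absolute log2 change of at least 1). For the difference between cytoplasm and nucleus, 3′ UTR ratio and expression gave 0 in each alternative without a library left out.

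Between nucleus and cytoplasm in control cells, 175 genes differed in 3′ UTR ratio, 289 with the replicate block, 28 with limma, 113 with a minimum mean of 50 reads, 48 in a fit of only the libraries compared, 99 after thinning and 8 to 242 with a library left out (8 without control cytoplasm replicate 1, 56 without control cytoplasm replicate 2 and 64 without control nucleus replicate 2). The cause was not tested.

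ZFC3H1 was lower in each fraction in every alternative. The total change passed in a fit of only the libraries compared (−0.77, adjusted p = 0.0368, 0.0928 to 0.999 in the others) and the nuclear change with the replicate block (−0.95, adjusted p = 0.0432, 0.0658 to 0.785 in the others). It was −0.80 to −0.74 in total, −0.51 to −0.29 in cytoplasm and −1.31 to −0.54 in nucleus with a library left out, and −0.10 in cytoplasm with aUTR reads added.

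Of 227 named results past the threshold, each a feature in 1 contrast, 99 stayed past it in the same direction under every alternative that tested the feature. The minimum absolute log2 change of 1 was left out of this tally, and 7 of the results fell short of it. Over the 2557 alternatives counted for these results, 2091 gave the same call, 465 did not pass and 1 reversed. Small changes can be missed at this depth and number of libraries. Of simulated 2-fold changes, 43.3% were recovered for IPA, 21.2% for the 3′ UTR ratio and 64.2% for expression. The 2 regions of a feature were simulated independently, so the shares for the ratios may be too low. As a separate alternative, thinning kept as little as 44.8% of a library's reads. DESeq2 size factors moved no count of genes or events by over 1.5 times. The pseudocount and filter alternatives fixed beforehand for normalized values, and a stricter threshold of the authors, were not run, since counts were at hand.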

Other observations

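The tests of IPA events and of cUTR reads below were planned before their results were seen, while the comparisons of nucleus and cytoplasm for expression and 3′ UTR ratio, their alternatives, and the library combinations matched by replicate number were chosen only after the result was seen.

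In control cells, cUTR reads also compare the share of each mRNA in the nuclear and in the cytoplasmic libraries. Values are scaled within each library, and neither the RNA amount per fraction nor the purity of the fractions was measured (0 nuclear long noncoding RNAs were listed), so they are relative levels and not locations. UTRN, which encodes the cytoskeletal protein utrophin, was 25.3-fold higher in the nucleus, 38.3 ± 6.01 against 1.45 ± 0.187 CPM (log2 change 4.66, SE 0.42, adjusted p = 1.62e-06, n = 2 each). IQGAP1 was at 649 ± 52.7 in the nucleus and 40.8 ± 9.57 in the cytoplasm (log2 change 3.98, SE 0.22), and COL12A1 (4.44), SPTBN1 (4.17), FBN2 (4.08) and ANLN (4.06) were higher in the nucleus as well. The ferritin mRNAs were relatively higher in the cytoplasm, with FTH1 at 128 ± 26.5 in the nucleus and 1463 ± 352 in the cytoplasm (log2 change −3.51, SE 0.23, adjusted p = 1.68e-07) and FTL at 57.3 ± 21.4 and 563 ± 279 (−3.29, SE 0.33, adjusted p = 3.68e-06). UBE2D4, ELK1 and EIF4EBP2 were lower in the nucleus too. Of 7654 genes 1806 were relatively higher in the nucleus and 1829 in the cytoplasm, and with aUTR reads added 4330 genes differed.

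Among the lists, 27 of 35 secreted, ER and matrix protein genes (median log2 change 1.40) were higher in the nucleus and 0 lower, as were 20 of 28 DNA damage genes (1.65) with 1 lower and 16 of 29 cell cycle genes (0.72) with 2 lower. ER carried into the nuclear fraction was not measured and stays open for the 1st of these lists. Of 35 ribosomal protein genes 30 were lower in the nucleus (median −1.17) and of 21 mitochondrial mRNAs 12 (−0.72), with 0 of either list higher. The set test at a preset correlation passed for these lists (adjusted p = 2.59e-09, 4.74e-06, 0.000245, 1.38e-09 and 0.000245), and with an estimated correlation for none of them (0.0603, 0.0557, 0.0557, 0.300 and 0.300). It also passed upward at the preset correlation for U1, SR protein and speckle factors (adjusted p = 0.00115), genes with well known IPA sites (0.00635), export factors (0.0112), PAXT, NEXT and exosome factors (0.0441) and cleavage and polyadenylation factors (0.0441), so that 8 lists moved up and 2 down, and with an estimated correlation for none of these either (adjusted p from 0.0854 to 0.385).

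The 3′ UTR ratio in control cells was higher in the nucleus for 114 genes and lower for 61. TOMM5, a mitochondrial import gene, went from 0.00292 ± 0.000761 aUTR reads per cUTR read in the cytoplasm to 0.0646 ± 0.0369 in the nucleus (log2 change 4.34, SE 0.36, adjusted p = 5.9e-05), and RAB3GAP2 from 248 ± 13.9 to 32.0 ± 1.94 (−2.94, SE 0.25, adjusted p = 5.9e-05). The numbers higher and lower were 24 and 40 without control nucleus replicate 2, 220 and 22 without control nucleus replicate 1, 4 and 4 without control cytoplasm replicate 1, and 34 and 22 without control cytoplasm replicate 2. Ribosomal protein genes moved up as a set at the preset correlation (5 of 32 higher, median 0.39, adjusted p = 0.000104) and secreted, ER and matrix protein genes down (0 of 35 past the threshold in edgeR, 3 at an unadjusted p under 0.05, adjusted p = 0.0459), neither with an estimated correlation (adjusted p = 0.557 for both).

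One hypothesis was that genes whose IPA usage rose lose full-length mRNA. Genes whose IPA usage rose in the nucleus had a median log2 change of cUTR reads in the cytoplasm of −0.06 and other genes with an IPA event of −0.03, a difference of −0.0306 (105 and 348 genes, permutation p = 0.479), with 61 of the 105 lower. In the other direction, genes whose IPA usage rose in the cytoplasm differed by −0.0564 in their nuclear cUTR reads (116 and 337 genes, permutation p = 0.123), so the difference asked for was not found in either test.

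Another hypothesis was that IPA transcripts rise more in the cytoplasm than in the nucleus. For the 120 events that rose in total RNA the rise in the cytoplasm exceeded that in the nucleus by a median of 0.466 on the log2 scale (medians 2.37 and 2.06), with 94 of the 120 larger in the cytoplasm and a median of −0.000502 for the other events. The permutation p over events was 1e-05, the smallest that the permutations can give, but events are not independent replicates. Over the 16 combinations of library pairs the median ran from −0.00846 to 0.965, with a SD of 0.281 and 1 median at or below 0. The prediction set beforehand asked for a median above 0 in all of them, so it failed. The miss was smaller than the SD, but the combinations share libraries, so the SD is not an independent spread. In the 4 combinations that match replicate numbers between the fractions the median ran from 0.192 to 0.830, but the labels do not say that fractions with the same number share a culture. These combinations were chosen after the result was seen, and the wider question stays open.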
